A study of Zea mays with 50 samples.

How the data were processed

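Small RNA libraries were made from the youngest wrapped leaf and from the shoot apical meristematic area of maize plants, per the labels, with the TruSeq small RNA kit, and were sequenced on a HiSeq2000. Each sample pooled several plants. Deposited values are read counts per distinct sequence (tag) in 1 table per library, with no gene names and no positions, and whole numbers throughout. The submitters' processing notes name cutadapt, FastQC and the genome build B73 RefGen_v3, with no versions, and how the build was used is not given in the sources used here. Tags were 15 to 47 nt long. Leaf libraries held 4201706 to 13273989 reads and those of the shoot apical meristematic area 28537273 to 37158747, so a tag absent from a leaf library is less tightly bounded than one absent from the other tissue. Reads carry no molecular identifiers.

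Samples were grouped by genotype, tissue, treatment and time as the labels give them, with replicate numbers from the labels. No 2 replicates of a group agreed within sampling noise: the chi-square per tag between replicates was 15.8 or more, against about 1 for repeat counts of 1 library. RPM values are reads of a tag scaled by all reads of its library. The features tested were miRNA families and all other single tags. A family was the sum of tags of 19 to 24 nt whose first 18 bases equalled a listed mature sequence, with 42 sequences in 27 families, and 1619 tags fell into families. The sequences and the lists of families were written from textbook knowledge, so a listed sequence may differ from that of these plants. Features entered a fit with at least 5 RPM in 3 libraries (wt leaf) or 2 libraries (all other fits). Related tags and tags of 1 precursor count as separate features, and reads that fit several family members cannot be told apart.

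Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, robust), with 1 mean per group and Benjamini-Hochberg adjustment over all features of a fit at 0.05. The genotype comparisons and the genotype by stress interaction used all 46 leaf libraries with total reads as library size. With the loss of a whole size class, TMM factors depend on which features are the majority. Total reads make the values shares of all reads, so the loss of 24-nt reads in rmr6-1 raised the other reads (1.16-fold as a share). Stress and time comparisons used the 24 wt or the 22 rmr6-1 leaf libraries, and tissue comparisons 10 libraries of wt at T0, each with TMM factors. Lists of families were tested with fry of limma 3.58.1 on log2 CPM with a prior count of 2, adjusted over the 7 lists; fry tests whether the members move, on balance, one way. The lists were phase change (miR156, miR172, miR529), auxin signalling (miR160, miR164, miR167, miR390, miR393, tasiR-ARF), organ patterning and growth (miR164, miR166, miR319, miR394, miR396), copper and oxidative stress (miR397, miR398, miR408, miR528), nutrient homeostasis (miR395, miR399, miR827), small RNA machinery (miR162, miR168) and drought and hormone linked (miR159, miR169, miR171, miR444, miR1432). Shares of 21-, 22- and 24-nt reads were compared with two-sided permutation tests within strata, exact where groups were small and otherwise with 100000 resamples, adjusted over the classes and comparisons of each question.

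Named items followed a rule. Families past 0.05 were named up to the 12 with the largest changes, with examples from each list. Single tags were the 5 largest rises and 5 largest falls past 0.05 with no overlap between the RPM values of the groups (for the mean over conditions, the same sign in all 8), leaving out tags that share 16 or more consecutive bases with a named one. A tag with 0 reads in a group is given as a bound against a floor of 3 reads over that group, and one with 1 to 3 reads as a pooled ratio with an exact 95% interval; both cover counting error only. The tests, lists, rule and most alternatives were fixed before the data were examined.

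The alternatives were other scalings (TMM factors, total reads, listed miRNA reads as library size), DESeq2 1.42.0 with its own size factors, filters of 2 and 20 RPM, the replicate number as a block, only the groups compared in the fit, exact listed sequences in place of families, and each library or replicate number left out in turn. Added after the data were seen were fits of families and tags of 20 to 24 nt with and without the block, fits without wt drought plus salt T0 replicate 1, the naming rule within 20 to 24 nt, 21- and 22-nt shares of the reads other than 24 nt, counts per size class under the other settings, the 43- and 47-nt tags without each control leaf library, the exact test of stress shares over sign changes within pairs of one replicate number, and the tests of shares between tissues over both treatments and between genotypes over time.

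Whether replicate numbers pair the samples was checked by the correlation of deviations from group means between libraries with the same number. For each wt stress comparison all 3 pairs were above 0.1 (lowest 0.112), as they were in rmr6-1 for drought and salt at T0 (lowest 0.446 and 0.433) and for drought and drought plus salt at T7 (lowest 0.296 and 0.593), so there the numbers were taken to pair the samples. The pairing comes from the data and not from the labels. The first principal component, with 46.2% of the variance in wt leaf and 44.7% in rmr6-1 leaf, separated the libraries of replicate number 1 from the others.

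The edgeR and DESeq2 steps were tested on simulated counts with 200 features changed by known folds. At 2-, 4- and 8-fold, edgeR recovered 43.3%, 88.1% and 100% for the genotype comparison over all conditions (32661 features), 0%, 2.99% and 33.3% for control leaves at T0, 0%, 2.99% and 10.6% for drought in wt leaf at T0 (21031 features), 0%, 4.48% and 28.8% for drought in rmr6-1 leaf at T0 (24678 features) and 0%, 0% and 12.1% for the tissue comparison (22811 features). For drought in wt leaf at T0, DESeq2 recovered 2.99%, 25.4% and 45.5%, with 26 false among 75 calls.

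Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 matplotlib 3.10.9 and the R package data.table (1.17.8). Gene-level tests of 24-nt counts were planned for use with a genome and were not run, and no tag was placed in the genome.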

Results

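Small RNAs were counted in 50 maize libraries, 46 from leaf and 4 from the shoot apical meristematic area, a tissue sample around the growing tip of the shoot. The leaf libraries came from wild-type (wt) plants (24 libraries) and from rmr6-1 plants (22 libraries). The rmr6 gene encodes the largest subunit of RNA polymerase IV, a plant enzyme that starts the production of most 24-nt small interfering RNAs, and rmr6-1 is a mutant allele of it. Plants were kept under control conditions, drought, salt or drought plus salt for 10 days, and were sampled at the end of that period (T0) or after 7 more days of recovery (T7). The labels call the replicates biological, and each was a pool of several plants. Each of the 16 leaf groups had 3 libraries, except rmr6-1 drought plus salt at T0 and rmr6-1 salt at T7 with 2 each. The shoot apical meristematic area was sampled in wt at T0, with 2 control and 2 drought libraries. Leaf libraries held 4201706 to 13273989 reads, and those of the shoot apical meristematic area held 28537273 to 37158747. Every value is a count of reads of one sequence (a tag) of 15 to 47 nt, and levels are given as RPM, the reads of a tag scaled by all reads of its library. No genome was used, so tags are named by sequence and carry no position.

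The first comparison asked how the small RNA population of the leaf changed in rmr6-1. The 24-nt class made up 17.8% ± 5.55 (SD, n = 24) of wt leaf reads and 4.68% ± 0.643 (SD, n = 22) of rmr6-1 leaf reads. The 2 other main size classes took larger shares of all reads in rmr6-1. The 21-nt class, the size of most miRNAs, rose from 3.85% ± 0.688 to 4.88% ± 0.705, and the 22-nt class rose from 7.81% ± 1.15 to 9.74% ± 1.14 (SD, n = 24 and 22). Counted over distinct tags, 24-nt tags made up 46.7% ± 6.26 of wt leaf tags and 5.72% ± 0.593 of rmr6-1 leaf tags (SD, n = 24 and 22). The lowest wt library had a 24-nt share of 10.96%, above the highest rmr6-1 library at 5.91%, so the 24-nt share separated the genotypes in all 46 libraries. The rmr6 transcript itself is outside what these libraries measure, and the 24-nt share is the check of the genotype labels.

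With genotype labels permuted within treatment and time, the two-sided permutation test gave a difference of -13.1 percentage points for the 24-nt class (adjusted p = 3e-05), and its raw p of 1e-05 is the smallest the 100000 resamples can give. The differences were 0.994 points for 21 nt (adjusted p = 7e-05) and 1.88 points for 22 nt (adjusted p = 3e-05), each by the same permutation test. As shares of the reads other than 24 nt, a denominator chosen after the data were seen, neither passed: 21 nt took 4.74% ± 1.16 in wt and 5.12% ± 0.764 in rmr6-1, and 22 nt 9.54% ± 1.58 and 10.2% ± 1.26 (SD, n = 24 and 22; permutation p = 0.281 and 0.178, adjusted p = 0.281 for both). Replicate numbers marked groups of libraries that differed in depth and content, and within numbers 1, 2 and 3 the 24-nt difference was -13.4, -11.6 and -14.1 points. In those same sets the 21-nt differences were 0.825, 1.37 and 0.994 points, and the 22-nt differences were 1.67, 1.66 and 2.56 points.

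**Figure D1:**
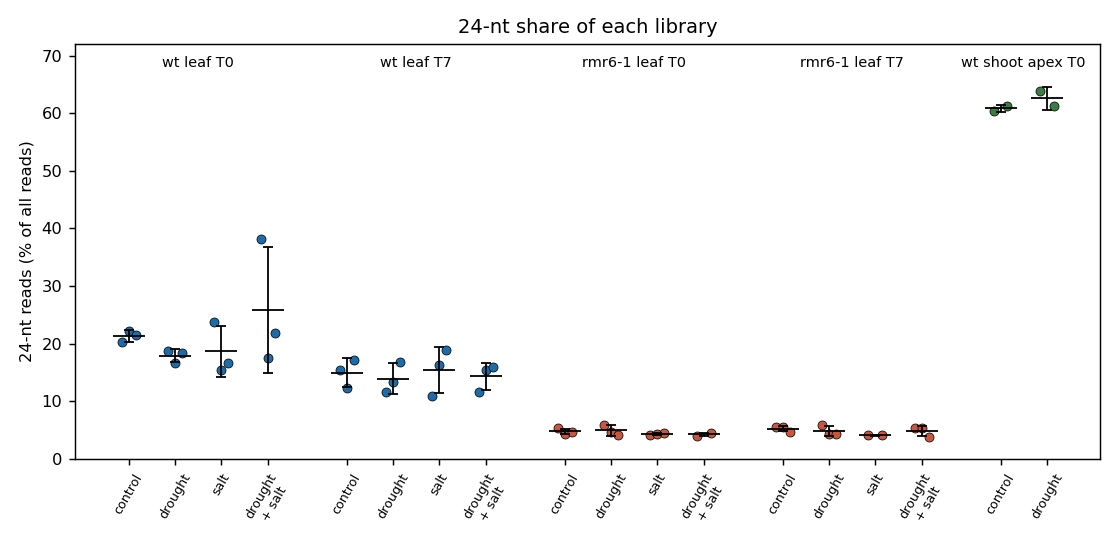
Share of reads that are 24 nt long (y axis, percent of all reads) in each of the 50 libraries, grouped on the x axis by genotype, tissue, time and treatment; points are libraries, horizontal lines are group means and bars are SD. The rmr6-1 leaf libraries lie between 3.80% and 5.91%, the wt leaf libraries between 10.96% and 38.2%, and those of the shoot apical meristematic area between 60.4% and 63.9%.

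**Figure D2:**
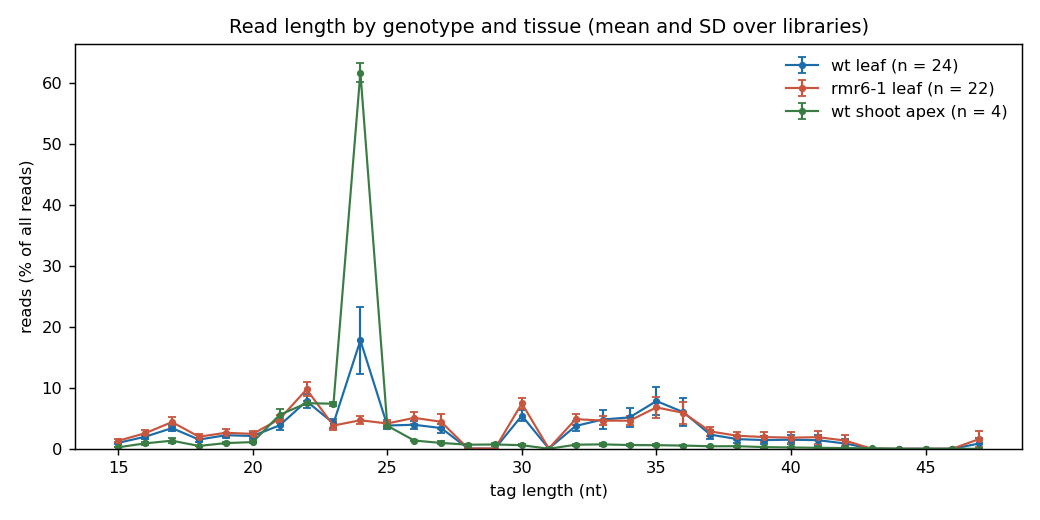
Mean share of reads (y axis, percent of all reads) at each tag length from 15 to 47 nt (x axis) in wt leaf (n = 24), rmr6-1 leaf (n = 22) and the wt shoot apical meristematic area (n = 4, called shoot apex in the plot); bars are SD over libraries. The 24-nt peak of the shoot apical meristematic area averaged 61.7% ± 1.51, that of wt leaf was 17.8% ± 5.55, and the 24-nt share of rmr6-1 leaf was 4.68% ± 0.643.

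Of 3643 single 24-nt tags tested between the genotypes, 2383 were lower in rmr6-1 and 457 were higher, with a median log2 fold change of -7.15. With total reads as library size, 762 of 2150 tags of 22 nt were higher and 255 lower, and of 1248 tags of 21 nt, 372 were higher and 164 lower; their medians were 0.32 and 0.23, against 0.31 for all features. Tags of 25 nt or more, outside the siRNA and miRNA sizes, had 8205 of 19994 higher and 2216 lower. With TMM factors the higher and lower counts were 376 and 382 for 22 nt, 192 and 251 for 21 nt and 3581 and 3546 for 25 nt or more. With DESeq2 they were 300 and 558, 142 and 369, and 2379 and 4751. The 24-nt class was mostly lower under both, with 2485 and 2604 tags lower and 211 and 142 higher. With a filter of 20 RPM, 595 tags of 24 nt were tested, of which 263 were lower and 154 higher, and their median was -0.43, against 0.34 for all features. The tag GGATCCGGACACACAGTAGAACAG (24 nt) had 96.7 ± 41.2 RPM in wt (SD, n = 24) and 2 reads in all 22 rmr6-1 libraries together, a pooled ratio of 7024 (95% exact counting interval 1944 to 58001). The tag AGAGAACGCTGACGTGGCACGTGA (24 nt) had 63.0 ± 19.3 RPM in wt and 5 reads in rmr6-1, a pooled ratio of 1730. The other 3 tags with the largest falls, AAGAACCGAGGAACCGAAGAACCG, AGAGAAGACTGTAAAGGACGGATA and ATCCCGCGAGAAACTAGGAACCCT, were also 24 nt long, with log2 fold changes of -11.87, -11.31 and -11.10 and 3, 2 and 3 reads in rmr6-1. Their pooled ratios were 5753 (interval 1968 to 27900), 4541 (1257 to 37497) and 3274 (1120 to 15876). Intervals and floors cover counting error only.

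Among the largest rises was AATGAGGTAGATGCTCCCGAGG (22 nt), with 90.2 ± 29 RPM in rmr6-1 (SD, n = 22) and 2 reads in the 24 wt libraries, a pooled ratio of 8887 (95% exact counting interval 2460 to 73392). The tag TACCAGGACGATAAAACGCGCATCTGAGCT (30 nt) had 33.4 ± 23.5 RPM in rmr6-1 and no read in wt, which makes it at least 2196-fold higher against a floor of 3 reads over the wt group. The remaining 3 were AATAATAGCTATGAGATCCGAGGGACT (27 nt, 128 ± 26.8 RPM against 6 wt reads), CTTTAATGGGAATCTCTCTGATGCCT (26 nt, 99.8 ± 67.1 against 7 wt reads) and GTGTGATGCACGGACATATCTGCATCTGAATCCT (34 nt, 64.2 ± 56.0 against 3 wt reads, a pooled ratio of 3855 with interval 1319 to 18698).

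A family was counted as all tags of 19 to 24 nt whose first 18 bases matched a listed miRNA sequence. Among these, 15 of the 22 measured rose in rmr6-1 and 1 fell, out of 27 listed. miR390, which triggers TAS3 tasiRNA production, rose by 0.89 ± 0.15 on the log2 scale (SE, adjusted p = 1.2e-05, edgeR), from 91.8 ± 31.8 to 167 ± 50.4 RPM (SD, n = 24 and 22). miR444, linked to MADS-box transcription factors, rose by 0.89 ± 0.31 (adjusted p = 0.018), and miR172, of AP2-type factors and the adult phase, by 0.73 ± 0.26 (adjusted p = 0.018). miR171 rose by 0.68, miR393 by 0.67, miR396 by 0.67, miR162 by 0.64, miR394 by 0.61, miR166 by 0.60, miR827 by 0.54, miR156 by 0.51 and miR167 by 0.51, with adjusted p from 0.0031 to 0.048. miR398, which targets copper/zinc superoxide dismutases, was the 1 family that fell, by -0.48 ± 0.17 (SE, adjusted p = 0.022); it lies outside the 12 families with the largest changes and was chosen after its value was seen.

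These rises depended on the scaling. The median of all features was 0.31 with total reads as library size, 0.01 with TMM factors, -0.14 with DESeq2 size factors and -0.20 with listed miRNA reads as library size. Relative to that median, miR390 was 0.58 higher, miR444 0.59 higher and miR398 -0.79. With TMM factors 1 family rose (miR390, 0.58) and 2 fell (miR398, -0.77, and miR528, -0.63), and with DESeq2 1 rose (miR390, 0.42) and 3 fell. With listed miRNA reads no family rose at adjusted p under 0.05 and 4 fell, and miR156, miR159, miR162, miR167, miR168, miR394 and miR827 turned to values between -0.11 and -0.01, which were 0.09 to 0.18 above the median of all features; miR159 was also at -0.05 with DESeq2. miR398 was lower under each of these scalings. Without the replicate 2 libraries 1 family passed (miR390, 0.75), without replicate 3 miR166, miR168, miR394, miR444 and miR827 did not, and without replicate 1 neither miR398 nor miR172 did. With the exact listed sequences in place of families miR162 turned to -0.80 ± 0.51 (SE, adjusted p = 0.18), a value that rests on 57 reads over all 50 libraries.

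By function, the auxin signalling list rose (fry, adjusted p = 0.00035), with 4 of 5 measured members higher (miR390, miR393, miR167 and miR164) and miR160 at 0.24. The organ patterning and growth list rose (adjusted p = 0.0094), with 4 of 5 members higher, among them miR166 and miR396, and the drought and hormone linked list rose (adjusted p = 0.0094) with all 3 members higher (miR159, miR171 and miR444). Phase change rose (adjusted p = 0.016) with miR156 and miR172 higher and miR529 at 0.13, and small RNA machinery rose (adjusted p = 0.045) with miR162 and miR168 higher. The copper and oxidative stress list fell (adjusted p = 0.018), with miR398 past the threshold and miR408 and miR528 at -0.20 and -0.32. Nutrient homeostasis did not pass (adjusted p = 0.20; 0.0082 without replicate 1), with miR827 higher and miR399 at -0.0023. Adjusted over the list alone, the same 15 and 1 families passed. With TMM factors none of the 5 rising lists passed (adjusted p from 0.22 to 0.61), and copper and oxidative stress did (adjusted p = 0.00029). Without replicate 2 none of these 6 lists passed, with adjusted p from 0.16 to 0.75, and without replicate 1 neither copper and oxidative stress (adjusted p = 0.10) nor phase change (adjusted p = 0.12) did.

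**Figure D3:**
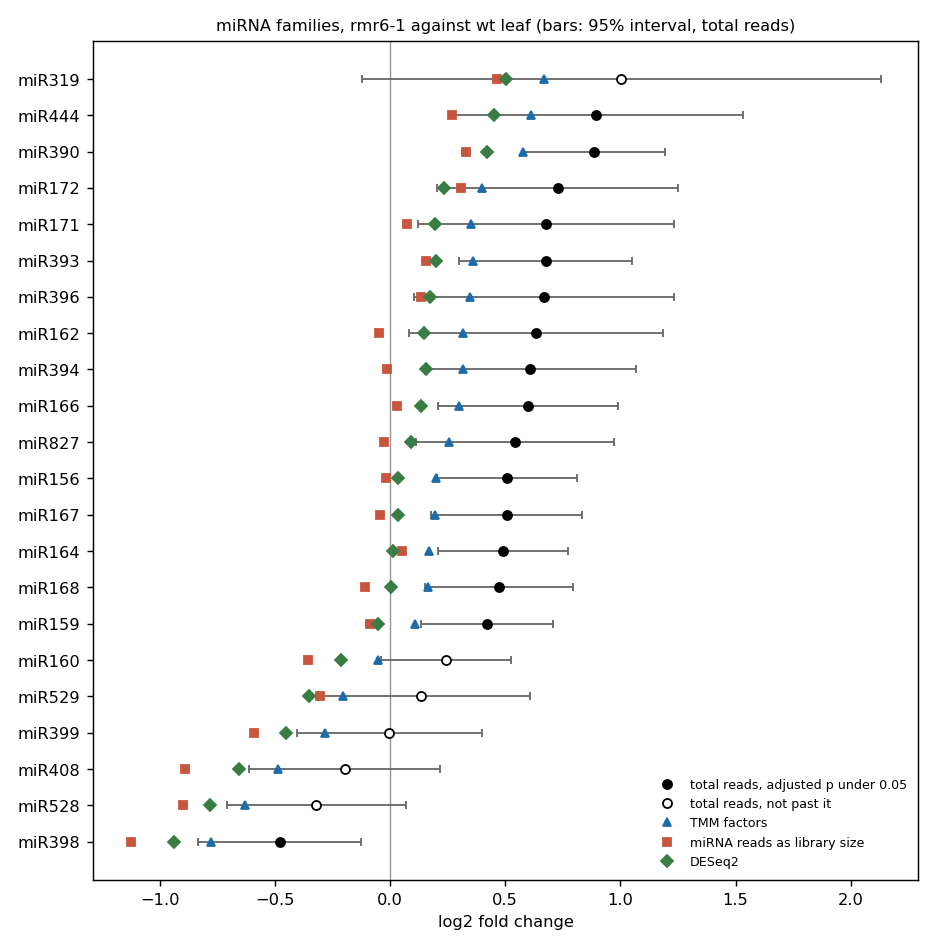
log2 fold change of each miRNA family between rmr6-1 and wt leaf (x axis), averaged over 8 conditions, 1 row per family; circles with 95% intervals use total reads as library size (filled where adjusted p is under 0.05), triangles TMM factors, squares listed miRNA reads and diamonds DESeq2. miR398 lies below 0 under all 4, miR390 above 0 under all 4, and miR156, miR159, miR162, miR167, miR168, miR394 and miR827 are above 0 with total reads and just below 0 with listed miRNA reads, miR159 also with DESeq2.

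Over all 32661 features, 17176 changed between the genotypes (11357 higher and 5819 lower in rmr6-1; edgeR, adjusted p under 0.05). The split depended on the scaling: 5100 higher and 7850 lower with TMM factors, 1193 and 8168 with listed miRNA reads, and 3455 and 9953 with DESeq2. Without replicate 2, 8529 features changed. Over families and tags of 20 to 24 nt alone, 2293 were higher and 3214 lower.

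In unstressed leaves at T0 alone, with 3 libraries per genotype, 2193 of 3643 tags of 24 nt were lower in rmr6-1 and 128 were higher. Of 19994 tags of 25 nt or more, 2003 were higher and 165 lower with total reads as library size, 877 and 335 with TMM factors, and 913 and 890 with DESeq2. The largest fall was AAGAACCGAGGAACCGAAGAACCG, at 135 ± 34.7 RPM in wt (SD, n = 3) and no read in rmr6-1, at least 900-fold lower against a floor of 3 reads over the group. The tag AAATACTGTAGAAGCCGCAGCCGC, named in this comparison and not in the one over all conditions, had 68.4 ± 7.47 RPM in wt and none in rmr6-1, at least 433-fold lower. The 27-nt tag AATAATAGCTATGAGATCCGAGGGACT was at least 1073-fold higher in rmr6-1, at 124 ± 28.5 RPM against none in wt. No miRNA family passed the threshold (edgeR). DESeq2 called 4 lower, miR398, miR408, miR528 and miR159, and with TMM factors 1 was lower, miR398. No list passed, and copper and oxidative stress came closest (adjusted p = 0.10), with the other 6 at 0.82 to 0.90; it fell with TMM factors (adjusted p = 0.0088) and when only these 6 libraries were fitted (adjusted p = 0.019). In all, 5254 features changed (2758 higher, 2496 lower; edgeR), 3382 without wt control replicate 1 and 3278 when only these 6 libraries were fitted (956 higher and 2322 lower). With TMM factors the split was 1244 higher and 2737 lower, and with DESeq2 1312 and 3621. The median of all features was 0.46 with total reads, 0.11 with TMM factors, -0.07 with DESeq2 and 1.04 with listed miRNA reads as library size.

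The next comparisons asked which small RNAs respond to drought and salt in the leaf. In wt leaf at T0, drought moved the 24-nt share from 21.3% ± 0.983 to 17.9% ± 1.08 (SD, n = 3), and in rmr6-1 leaf the drought minus control difference was 0.166 points. Over both genotypes the drought difference was -1.62 points (exact permutation p = 0.07, adjusted p = 0.895), the lowest p of the 18 tests of 21-, 22- and 24-nt shares, so no stress passed for any class at T0 or T7. That test left the replicate numbers out; within pairs of one number, a test chosen after the data were seen, the wt share was lower under drought in 3 of 3 pairs (exact p = 0.25, the smallest 3 pairs can give). For the 24-nt share under drought at T0 over the 6 pairs of both genotypes the exact p was 0.188 (adjusted p = 0.875). All 3 pairs moved one way in 1 of 18 such sets of wt and 6 of 12 of rmr6-1, where chance gives 25% and sets share their control libraries. In rmr6-1 these were lower 24-nt shares under salt at T0 and after drought plus salt at T7 (-0.461 and -0.456 points) and lower 21-nt shares after drought and drought plus salt at T7 (-0.316 and -0.611 points). The other two were higher 21- and 22-nt shares under drought at T0 (0.418 and 0.709 points). miR396, of GRF transcription factors, was at 4.998 ± 1.08 RPM under drought and 20.9 ± 4.40 in control (SD, n = 3) in wt leaf at T0, a log2 fold change of -2.11 with adjusted p = 0.60. miR167 was at -1.20 (adjusted p = 0.70), miR319 at -2.25 (adjusted p = 0.82) and miR398 at 0.51 (adjusted p = 0.85) in the same edgeR comparison. No list passed at T0 in wt leaf under drought (fry, adjusted p from 0.098 to 0.30), salt (0.85 to 0.95) or drought plus salt (0.73 to 0.95). With the replicate number as a block, drought and hormone linked, with miR159 as its 1 measured member, fell under drought (adjusted p = 0.043). It and organ patterning and growth also fell when only the groups compared were fitted (adjusted p = 0.029 for each).

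No feature of 21031 passed in wt leaf at T0 under drought, salt or drought plus salt (edgeR). At an unadjusted p under 0.05 the counts were 1479, 165 and 924, and DESeq2 called 78, 2 and 0. In rmr6-1 leaf at T0 no feature of 24678 passed under drought, salt or drought plus salt (edgeR), with 2401, 2477 and 2355 at an unadjusted p under 0.05 and 726, 636 and 355 by DESeq2. With the replicate number as a block, 489 features passed under drought (32 higher and 457 lower) and 521 under salt (48 higher and 473 lower) in rmr6-1 leaf at T0. None of the 22 miRNA families was among them, which says little with 489 and 521 calls among 24678 features. Of the 457 lower tags 118 (25.8%) were 20 to 24 nt long, near the 22.5% of all features tested. The median level of these 457 tags was 14.5 and 17.1 RPM in rmr6-1 control T0 replicates 2 and 3, 4.31 in replicate 1, and 14.1 and 10.7 in wt drought T0 replicate 2 and wt salt T0 replicate 1. In the other leaf libraries it lay between 1.32 and 7.2. Without rmr6-1 control T0 replicate 1, 804, 684 and 283 features passed for drought, salt and drought plus salt. In simulated data for these designs only few of the features were changed. Of those changed 8-fold, edgeR recovered 10.6% for drought in wt leaf at T0 and 28.8% for drought in rmr6-1 leaf at T0. Smaller changes limited to few features were thus mostly not detectable with 3 libraries per group. A response of many features at once was not simulated, so these figures do not bound one. For the tissue comparison such a simulation recovered 12.1% at 8-fold, while the real fit called 16394 of 22811 features.

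Whether the 2 genotypes responded differently at T0 was tested as an interaction over the 3 stresses, and no feature of 32661 passed (edgeR; 2139 at an unadjusted p under 0.05; 7 by DESeq2). For miRNA families, drought in rmr6-1 leaf at T0 gave -1.21 for miR172, 2.92 for miR319 and 0.64 for miR398 on the log2 scale, with adjusted p of 0.62, 0.63 and 0.88.

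After 7 days of recovery, the copper and oxidative stress list was higher in previously droughted wt leaf than in control at T7 (fry, adjusted p = 0.0013) and after drought plus salt (adjusted p = 0.0029), and after salt it did not pass (adjusted p = 0.099; 0.034 without wt salt T7 replicate 3). Adjusted over the list alone, miR408, which targets copper proteins, rose by 1.33 ± 0.38 after drought (SE, adjusted p = 0.038) and by 1.31 ± 0.38 after drought plus salt (adjusted p = 0.044), and miR398 rose by 1.33 ± 0.42 after drought (adjusted p = 0.041). miR408 was at 14.2 ± 1.58 RPM after drought and 7.71 ± 2.85 in control (SD, n = 3). miR528 was at 1.10 after drought and 1.02 after drought plus salt, and did not pass. Over all features none of these families passed (edgeR), and DESeq2 called miR408 after drought (adjusted p = 0.029). The phase change list had miR156 as its 1 measured member, so fry tested that family alone. The list was higher after drought (fry, adjusted p = 0.0039), salt (adjusted p = 0.0058) and drought plus salt (adjusted p = 0.021), with miR156 at 0.95, 0.98 and 0.76. By edgeR miR156 passed in none of these 3 comparisons, neither over all features nor adjusted over the list alone. The other 5 lists did not pass in any of the 3 T7 comparisons, with adjusted p from 0.33 to 0.88; without wt control T7 replicate 3 auxin signalling was higher after drought (adjusted p = 0.049).

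With listed miRNA reads as library size the copper list did not pass (adjusted p = 0.80 after drought and 0.47 after drought plus salt), and after drought plus salt it was at 0.0505 when only the groups compared were fitted. Nor did phase change pass with listed miRNA reads or with total reads (adjusted p from 0.094 to 0.32 with the latter), and after drought plus salt it did not without wt control T7 replicate 2 or drought plus salt replicate 2 or 3 (adjusted p = 0.14, 0.067 and 0.083). miR398, miR408 and miR156 stayed above 0 under each scaling. The median of all features after drought was 0.10 with TMM factors, -0.30 with total reads and -0.45 with listed miRNA reads, and relative to it miR408 was at 1.23, 1.17 and 1.16 and miR398 at 1.23, 1.21 and 1.18. The 3 comparisons shared the same 3 control libraries, and those libraries were low in miRNA families against control at T0. All 7 lists were lower in control leaf at T7 than at T0 (fry, adjusted p from 5.4e-05 to 0.011), and 12 of 17 families were lower adjusted over the list alone and 0 over all features (edgeR; 5 by DESeq2). miR408 was at 7.71 ± 2.85 RPM at T7 and 25.9 ± 8.38 at T0 (SD, n = 3), and miR156 at 19.3 ± 6.37 and 44.9 ± 10.5. The median of all features was -0.09 with TMM factors, 0.19 with total reads and 1.63 with listed miRNA reads, and relative to it miR408 was at -1.93 with each and miR156 at -1.39, -1.40 and -1.41. With listed miRNA reads as library size, before the median is taken off, miR156, miR159, miR160, miR164, miR168, miR390, miR398 and miR399 had values between 0.19 and 1.00 and no list passed. Relative to the median of that scaling these 8 were between -1.44 and -0.63. Without wt control T7 replicate 2, auxin signalling, nutrient homeostasis, organ patterning and growth, small RNA machinery and drought and hormone linked (miR159 its 1 measured member) no longer passed, with adjusted p from 0.055 to 0.066.

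No feature passed in wt leaf at T7 after drought, salt or drought plus salt (edgeR; 2238, 597 and 393 at an unadjusted p under 0.05; 213, 0 and 0 by DESeq2), nor between control leaves at T7 and T0 (1280 unadjusted; 58 by DESeq2; 3538 with listed miRNA reads as library size). In rmr6-1 leaf at T7 no feature passed after drought, salt or drought plus salt (edgeR; 263, 1167 and 482 unadjusted; 0 in each by DESeq2), and without rmr6-1 salt T7 replicate 2, 16 passed after salt. No list passed in rmr6-1 leaf under any stress at T0 (adjusted p from 0.66 to 0.89) or T7 (0.15 to 0.97); with listed miRNA reads as library size copper and oxidative stress was higher after salt at T7 (adjusted p = 0.018).

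The last comparisons set the shoot apical meristematic area against leaf in wt control plants at T0. Its 24-nt share was 60.9% ± 0.610 (SD, n = 2), against 21.3% ± 0.983 in leaf (SD, n = 3). An exact permutation test of these 5 libraries gave p = 0.1, the smallest it can give, and over control and drought libraries together, a test chosen after the data were seen, the difference was 42.1 points (exact permutation p = 0.01, the smallest it can give, adjusted p = 0.03). The size of this difference depended on what was counted: over reads of 20 to 24 nt it was 22.6 points, and over distinct tags 14.7 points. The difference over all reads did not pass without any 1 of the 5 control libraries (adjusted p = 0.050 without a leaf and 0.075 without a shoot apical meristematic area library), where fewer relabellings are possible. With TMM factors, of 7752 single 24-nt tags 6016 were higher and 498 lower in the shoot apical meristematic area, and of 9359 tags of 25 nt or more 365 were higher and 5634 lower. For the 24-nt tags these counts were 5830 and 559 with total reads, 1824 and 901 with listed miRNA reads, and 1852 and 1344 over features of 20 to 24 nt. For the longer tags they were 357 and 5760 with total reads and 300 and 7333 with listed miRNA reads.

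miR319, which targets TCP transcription factors, was 62.9-fold higher in the shoot apical meristematic area, at 653 ± 133 RPM (SD, n = 2) against 12.5 ± 15.2 in leaf (SD, n = 3). Its log2 fold change of 5.97 moved to 4.08 over features of 20 to 24 nt, 4.39 with listed miRNA reads, 5.22 and 7.28 with filters of 2 and 20 RPM, and 5.13 and 7.71 without leaf control replicate 1 or 3. miR529, of SPL transcription factors, rose 10.8-fold (log2 3.44 ± 0.59, SE, adjusted p = 0.00034), miR159, of GAMYB factors, by 1.95 and miR166, of HD-ZIP III factors, by 1.87. The families that fell were miR408 (-3.44), miR160 (-3.14), miR398 (-2.99), miR167 (-2.78), miR164 (-2.34), miR528 (-1.35) and miR156 (-1.25), with adjusted p from 0.00048 to 0.043. In all, 4 of 17 measured families rose and 7 fell with TMM factors over all features, and the same numbers passed adjusted over the list alone. The split differed under other settings: miR162 also passed, as lower, with listed miRNA reads and over features of 20 to 24 nt. The median of all features was -0.60 with TMM factors, -0.86 with total reads, -0.79 with DESeq2 and -2.18 with listed miRNA reads; relative to the first, miR319 was at 6.57 and miR408 at -2.85. miR159 and miR166 were at 0.24 and 0.15 with listed miRNA reads (2.42 and 2.33 relative to the median) and did not pass. Most listed miRNA reads were of miR166 itself, 977527 of 1036477 in shoot apical meristematic area control replicate 1. In leaf control T0 replicate 1 they were 125006 of 146677. That scaling thus holds miR166 near 0 and cannot test it. When families and tags of 20 to 24 nt alone were tested, miR166 turned to -0.08. With a filter of 20 RPM miR156 turned to 0.06 and miR528 was at -0.04. Without shoot apical meristematic area control replicate 1, 7 families passed, and miR156, miR159, miR166 and miR528 did not. Neither miR156 nor miR528 passed without shoot apical meristematic area control replicate 2 or without leaf control replicate 3, and without leaf control replicate 2 miR156 did not.

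By list, auxin signalling fell (fry, adjusted p = 0.0047), with miR160, miR167 and miR164 lower and miR390 at -0.56, and copper and oxidative stress fell (adjusted p = 0.0046) with all 3 of its measured members lower. Drought and hormone linked, with miR159 as its 1 measured member, rose (adjusted p = 0.0049) and did not pass with listed miRNA reads (adjusted p = 0.28) or over 20 to 24 nt (adjusted p = 0.97). Organ patterning and growth rose (adjusted p = 0.042), with miR319 and miR166 higher and miR164 lower, and it fell over features of 20 to 24 nt (adjusted p = 0.00052). With listed miRNA reads it was lower (adjusted p = 0.0015) before the median of -2.18 is taken off, and relative to that median miR319 was at 6.57 and miR166 at 2.33. Its rise ended without leaf control replicate 1 or 2 or without shoot apical meristematic area control replicate 1 (adjusted p = 0.18, 0.072 and 0.23). Phase change (adjusted p = 0.082), small RNA machinery (adjusted p = 0.65) and nutrient homeostasis (adjusted p = 0.72) did not pass. With a filter of 20 RPM phase change and small RNA machinery rose (adjusted p = 0.00048 and 0.022).

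**Figure D4:**
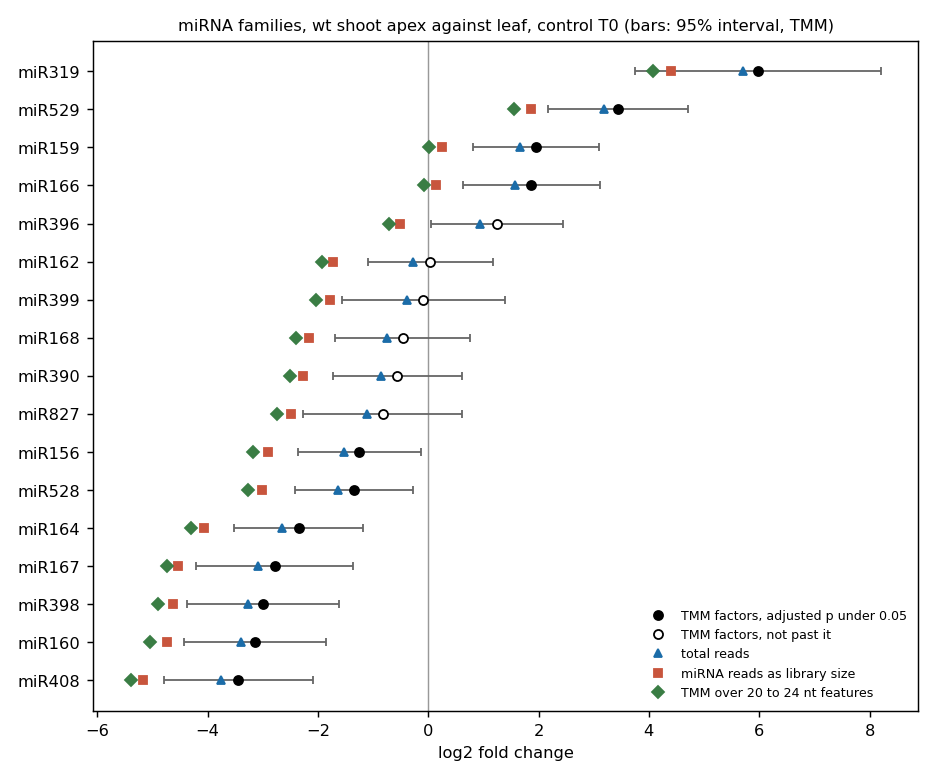
log2 fold change of each miRNA family between the wt shoot apical meristematic area (n = 2) and leaf (n = 3) in control plants at T0 (x axis), 1 row per family; circles with 95% intervals use TMM factors (filled where adjusted p is under 0.05), triangles total reads, squares listed miRNA reads and diamonds TMM factors over features of 20 to 24 nt. miR319 and miR529 lie above 0 and miR408, miR160, miR398, miR167, miR164, miR528 and miR156 below 0 under all 4, while miR159 and miR166 are near 0 under the last 2.

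Over all 22811 features, 8215 were higher and 8179 lower in the shoot apical meristematic area (edgeR), against 2793 higher and 11339 lower with listed miRNA reads as library size. Of the 16383 single tags called, 41.5% lay outside 20 to 24 nt. Of the 22794 single tags tested, 12017 were 20 to 24 nt long, so the called tags held no excess of other lengths. The 5 largest single-tag rises were all 43 nt long and 4 of the 5 largest falls were 47 nt long. All 16 tags of 43 nt that were called were higher and all 48 of 47 nt were lower, and 5 of the 16 were the last 43 bases of 1 of the 48. Reads of 43 nt made up 0.0849% of the shoot apical meristematic area and 7.3e-05% of wt leaf, and reads of 47 nt 0.00478% and 0.870%. The 47-nt share of wt leaf was lowest in replicate 1, at 0.0327 to 0.0800%, with 0.136 to 2.35% in replicate 2 and 0.469 to 2.49% in replicate 3. In the 3 control leaf libraries at T0 it was 0.0462%, 0.136% and 2.08%, and without each of these in turn 49, 47 and 42 tags of 47 nt were called lower. Some lengths were nearly missing from the files. In wt leaf, reads of 28, 29 and 31 nt made up 0.0380%, 0.0272% and 0.0402%, beside 3.40% at 27 nt and 5.43% at 30 nt, and reads of 42 nt made up 0.875%. In the shoot apical meristematic area, reads of 31 nt made up 0.00498% and those of 44 nt 2e-05%. Reads of 28 and 29 nt together made up 0.0398 to 0.137% of leaf libraries and 1.06 to 1.92% of those of the shoot apical meristematic area. The nearly missing lengths thus differed between the tissues. Whether read length or trimming differed is not given in the sources used here, so no fold is given for tags of 43 or 47 nt. For the 24-nt share and the counts of longer tags too, such a difference cannot be told apart from tissue.

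Applied within 20 to 24 nt, a restriction chosen after the data were seen, the same rule named GGAGAGAGAAGATAGAGTTGGATT (24 nt, at least 66.2-fold higher) and GCCCACTGAAGACAATGTTCCC (22 nt, at least 61.9-fold higher) among the rises. Among the falls it named GTTCGCAAGAATGAAACTCAAA (22 nt), at 59.3 ± 28.8 RPM in leaf (SD, n = 3) and none in the shoot apical meristematic area, at least 1339-fold lower.

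Drought changed no feature in the shoot apical meristematic area at T0 (edgeR; 602 of 22811 at an unadjusted p under 0.05; 46 by DESeq2, all lower). miR319 was at 583 ± 161 RPM under drought and 653 ± 133 in control (SD, n = 2), and miR396 was at 40.9 ± 15.4 and 39.9 ± 16.7. No list passed, with adjusted p from 0.80 to 0.96. Neither did any list in the difference between tissues (adjusted p = 0.99 in all 7). No feature differed between the tissues in its drought response (edgeR; 484 unadjusted; 1 by DESeq2). In simulated data for the drought comparison in this tissue, again with few features changed, edgeR recovered 6.06% of features changed 8-fold.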

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

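The tests of the difference between genotypes over time and the 3 tests of what could account for it were chosen only after the result was seen. The change of the 24-nt share from T0 to T7 differed between the genotypes. In wt leaf the share was 20.9% ± 6.01 at T0 and 14.6% ± 2.60 at T7 (SD, n = 12 each), and it was lower at T7 in 4 of 4 treatments. Without replicate number 1 it was lower in 3 of 4: under salt, replicate 1 was at 23.7% at T0 and 10.96% at T7, replicate 2 at 15.5% and 16.3%, and replicate 3 at 16.7% and 18.9%. In rmr6-1 leaf it was 4.57% at T0 and 4.79% at T7 (n = 11 each), lower in 2 of 4 treatments. The difference between these changes was 6.49 points (permutation p = 0.00024, adjusted p = 0.0014), and over distinct 24-nt tags 7.46 points (permutation p = 0.0025, adjusted p = 0.0075).

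A larger load of longer fragments at T7 is argued against, since over reads of 20 to 24 nt alone the difference was 8.98 points (permutation p = 0.0015). The highest wt library, drought plus salt T0 replicate 1, was at 38.2% (95% Wilson interval 38.15 to 38.21) against 17.5% and 21.8% in its mates, and without it the difference was 4.94 points (permutation p = 5e-04), which argues against that library as the whole cause. Without the libraries of replicate number 1 the difference was 3.16 points (permutation p = 0.030, adjusted p = 0.091), so a contribution of whatever sets those libraries apart cannot be told apart from a change over time. A change with leaf age or recovery that needs RNA polymerase IV may remain as a hypothesis; the share in rmr6-1 was low at both times, which leaves little room for a fall there.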

How the results depend on the processing

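Fits of families and tags of 20 to 24 nt, fits without wt drought plus salt T0 replicate 1, the paired tests of shares under stress, the 21- and 22-nt shares of reads other than 24 nt, the size classes under other settings, the 47-nt tags without each control leaf library, and all tests of the tissue share over both treatments and of genotype by time were chosen only after the data were seen. Among the counts and shares that answer comparisons, 306 values under alternatives stayed on their side or within 1.5 times, 45 moved further and 6 lost significance. The 306 include counts of 0 that stayed at 0, such as 23 for the interaction with libraries left out. Such counts say little, since fits of few libraries detect few changes. Among values of single families, tags, lists and shares, 1488 stayed, 131 lost significance, 32 gained it and 37 changed direction. Where a value below moved, the cause was not tested, except that stricter filters, length limits and left-out libraries test fewer features or samples. Depth limits leaf libraries most. The 4 gene-level tests of 24-nt counts were not run.

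For rmr6-1 against wt leaf, the count of 17176 became 9361 with listed miRNA reads as library size, 38679 and 4437 with filters of 2 and 20 RPM, 5507 over 20 to 24 nt and 6050 with the replicate block too; replicates left out gave 8529 to 17103. In control leaves at T0, 5254 became 15785 and 986 with those filters, 9848 with the replicate block, 3147 over 20 to 24 nt and 3278 with only the groups compared, and 3382 to 5282 with libraries left out. No family passed in control leaves at T0, against 1 lower with the block (miR398, -1.17) and with the block over 20 to 24 nt; over all conditions families changed numbered 3 with TMM factors, 4 with listed miRNA reads and 4 with DESeq2, against 16, and 1 to 17 with replicates left out. DESeq2 called 7 features for the interaction, 78, 2 and 213 for wt drought T0, salt T0 and drought T7, 58 over time in wt controls, 726, 636 and 355 for rmr6-1 drought, salt and drought plus salt at T0, 46 for drought in the shoot apical meristematic area and 1 for tissue by drought, where edgeR called 0.

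Between control leaves at T7 and T0, 3538 features passed with listed miRNA reads, 1 with the replicate block and 127 over 20 to 24 nt with the block. In rmr6-1 leaf at T0, drought gave 489 with the block, 223 over 20 to 24 nt and 361 with both, and salt gave 521, 90 and 286. The block also made the drought and hormone linked list pass under drought in wt leaf at T0 and changed no other count of calls and no other list where numbers pair the samples. Over 20 to 24 nt the phase change list was higher there (adjusted p = 0.0021). Libraries left out gave 0 to 804 features for drought, 0 to 684 for salt and 0 to 283 for drought plus salt in rmr6-1 leaf at T0, and 0 to 16 for salt at T7. The numbers do not pair the samples in the genotype, time and tissue comparisons. Across the leaf libraries the lowest correlation was -0.316, and the median was 0.397 within a number and -0.163 between numbers. Of 46 libraries 44 lay closest to their own number, a hint from the data and not the design.

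For the tissues, 16394 features became 42607 and 2783 with filters of 2 and 20 RPM, 6038 over 20 to 24 nt and 6245 with the block too, and 11609 to 15412 with libraries left out. Families numbered 17 with the filter of 2 RPM, and 7 to 12 with libraries left out. The 24-nt share difference was 41.8 to 42.3 points with libraries left out, past the threshold in none (adjusted p from 0.050 to 0.075, with fewer relabellings). With all libraries kept it was 22.6 points over reads of 20 to 24 nt and 14.7 points over distinct tags. The genotype by time difference was 3.16 to 8.66 points with libraries left out.

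Directions of results past the threshold turned in the cases below, with some that had not passed. Listed miRNA reads as library size is built from the families tested, mostly miR166. It moves the median of all features to -0.20 between genotypes, 1.63 over time and -2.18 between tissues, so turns under it are not changes relative to that median. Tags of 25 nt or more were 19994 of the 32661 features between genotypes and 9359 of 22811 between tissues, so the median is not one of small RNA sizes alone. Over features of 20 to 24 nt, some families and lists between tissues turned as well, as given below. Relative to the median of all features, miR156 was at -1.41 over time with listed miRNA reads and -1.39 with TMM factors, and miR319 at 6.57 between tissues with both. For rmr6-1 against wt, listed miRNA reads gave miR156 -0.0187, miR162 -0.0476, miR167 -0.0418, miR394 -0.0122, miR827 -0.0270, miR159 -0.0866 and miR168 -0.107, and DESeq2 gave miR159 -0.05; miR162 was -0.80 with exact sequences (57 reads in all) and between -0.10 (without replicate 2) and 0.92 with replicates left out. Between control leaves at T7 and T0, listed miRNA reads gave miR156 0.22, miR159 0.25, miR160 0.47 and miR399 0.19, and of families not past the threshold miR398 1.00, miR168 0.84, miR164 0.83 and miR390 0.55. For the tissues miR156 was 0.0603 with a filter of 20, miR166 -0.0794 over 20 to 24 nt and -0.12 with the block too, and miR159 -0.0060 there; miR319 was 7.55 with the block. Of the 6 families not past the threshold between tissues, all 6 turned somewhere, in 16 of 60 values: miR396 (1.25) to -0.52 with listed miRNA reads, -0.72 over 20 to 24 nt and -0.91 with the block too, miR390, miR168, miR827 and miR399 to 0.75, 0.84, 0.48 and 1.21 with a filter of 20, and miR162 (0.04) to -1.92 over 20 to 24 nt (adjusted p = 0.0055) and -1.72 with listed miRNA reads (adjusted p = 0.017). In each other comparison 3 to 14 such families turned, in 8 to 27 values, and none passed there. Lists turned with listed miRNA reads: phase change (adjusted p = 0.74) and small RNA machinery (adjusted p = 0.54) between genotypes; auxin signalling (adjusted p = 0.52), copper and oxidative stress (adjusted p = 0.99), drought and hormone linked (adjusted p = 0.83), phase change (adjusted p = 0.89) and small RNA machinery (adjusted p = 0.83) over time; and organ patterning and growth between tissues (adjusted p = 0.0015). Between tissues, organ patterning and growth also turned with a filter of 2 (adjusted p = 0.38), over 20 to 24 nt (adjusted p = 0.00052) and with the block too (adjusted p = 0.13), and drought and hormone linked with a filter of 2 (adjusted p = 0.21) and over 20 to 24 nt with the block (adjusted p = 0.96). Phase change, which had not passed between tissues, was lower with listed miRNA reads (adjusted p = 0.028; miR156 -0.72 and miR529 4.05 relative to the median) and fell over 20 to 24 nt (adjusted p = 0.00035) and with the block too (adjusted p = 0.0053), and small RNA machinery rose with a filter of 20 (adjusted p = 0.022). Of the stress differences in share, 6 of 30 values at 21 nt, 5 of 30 at 22 nt and 1 of 30 at 24 nt turned with no library left out; at 22 nt salt went from -0.587 to 2.39 at T7 and from -0.429 to 0.742 at T0 over reads of 20 to 24 nt, and at 21 nt drought at T7 from -0.134 to 0.527. The 24-nt share difference for salt at T7 was 0.103 over reads of 20 to 24 nt, and -1.20 to 0.944 points with replicates left out. For drought plus salt it was -1.21 to 4.32 at T0 with replicates left out, -1.08 without wt drought plus salt T0 replicate 1, and -1.54 to 0.174 at T7; the turned values were those without replicate 1.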

Other observations

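Except the test for tags that differ at 1 base, the tests in this part were chosen only after the results were seen. The first base of distinct 24-nt tags differed between the genotypes. A 5′ A was found in 52.6% ± 0.807 of distinct 24-nt tags in wt leaf (SD, n = 24) and in 36.0% ± 1.17 in rmr6-1 leaf (SD, n = 22), a difference of -16.5 points (permutation p = 1e-05, the smallest 100000 resamples can give, adjusted p = 4e-05). A 5′ T was found in 10.1% ± 0.881 and 20.2% ± 0.634. Counted over reads, 24-nt reads with 5′ A made up 50.01% in wt and 21.5% in rmr6-1, and those with 5′ T 15.5% and 41.1%. In the shoot apical meristematic area 47.7% ± 0.264 of distinct 24-nt tags began with A (SD, n = 4).

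The tasiR-ARF family, the TAS3 small RNAs that target auxin response factors, had 34, 49, 40 and 38 reads in the 4 libraries of the shoot apical meristematic area and 0 to 5 in leaf libraries, which were shallower, and it did not pass the filter. No read matched the listed tasiR-ARF sequences over their full length. Those sequences were written from textbook knowledge, and whether they or the plants account for this was not tested.

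Of tags other than 24 nt, 246 were called at least 32-fold higher in rmr6-1 leaf and 67 at least 32-fold lower. The loss of 24-nt reads raised all other reads as a share by 1.16-fold, far below the 32-fold by which the tags were chosen, so it cannot be their whole cause. For 15 of the 246 (6.1%) a tag 1 substitution away was called lower in rmr6-1, against 5 of 1230 length-matched tags (0.407%; Fisher's exact test, p = 1.03e-08), which goes with a sequence variant of the rmr6-1 plants. That test takes tags as independent, while related tags and tags of 1 precursor count separately here, so its p may be too small. Against a variant, 0 of the 67 lower tags had such a tag called higher. The lower partners of the 15 were at log2 -2.87 to -1.02, not lost, so a variant stays open for them. For the other 231 (93.9%) a variant that differs in more than 1 base, at the ends or by an insertion or deletion cannot be told apart from an effect of rmr6-1, because no genome of the stock was used here; the labels give the B73 background for both genotypes.

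Under drought in rmr6-1 leaf at T0, 457 tags were lower with the replicate number as a block; their median level was 14.5 and 17.1 RPM in control replicates 2 and 3, 4.31 in control replicate 1 and 1.43 to 2.79 under drought. Whether they are fragments of longer RNA is open: 16.8% were 21, 22 or 24 nt long, against 15.5% of all features tested, but 24 nt took 8.32% against 4.67% and 22 nt 4.60% against 7.03%, so the lengths do not settle it. A drought response common to both genotypes was tested by their change in wt leaf: over the 348 tags that passed the filter in wt the median log2 fold change was 0.839 (quartiles 0.227 and 1.42). Over all 457, a version chosen after that first value was seen, it was 1.17 (quartiles 0.483 and 1.74), and without wt drought T0 replicate 2, where the tags' median level was 14.1 RPM, it was -0.364 (quartiles -0.892 and 0.149). The direction thus rests on 1 library, and a common response cannot be told apart from its absence.

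Whether chance can be excluded was examined by splitting the same libraries in other ways. For the genotype comparison over all conditions 1 of 50 splits, the real one, gave 17176 features, and the highest other gave 1440. The rank of the real split argues against chance. Here and for control leaves at T0 the other splits mix the genotypes within groups, which widens the spread of their fits. Their low counts thus follow in part from the procedure, and the size of the gap does not measure chance. For control leaves at T0, 3 against 3 libraries give 10 splits, too few for a share under 0.05; the real split gave 5254 features and the highest other 0. For the stress and time comparisons of 3 against 3 libraries, all 10 of 10 splits gave 0, and 10 splits are too few. At an unadjusted p under 0.05 the highest other split exceeded the real one in each of these, for example 7510 against 263 for drought in rmr6-1 leaf at T7 and 4866 against 597 for salt in wt leaf at T7, which points to a structure of the samples. Numbers pair the samples in 10 of these comparisons, and in all 10 the highest other split put 2 libraries of one number on the same side. Among the 4 splits of each that part all pairs, the real one was the highest in 8 of 10, for example 2238 against 250 for drought in wt leaf at T7 and 1479 against 355 for drought in wt leaf at T0. It was barely so for salt in rmr6-1 leaf at T0 (2477 against 2419) and drought plus salt in wt leaf at T0 (924 against 921). The exceptions were salt in wt leaf at T0 (165 against 779) and drought in rmr6-1 leaf at T7 (263 against 430). With 4 such splits no share under 0.05 can be had. Comparisons of the same genotype and time also share their control libraries, so the 10 are not independent.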
